A study of Homo sapiens with 3 samples.

How the data were processed

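The samples were 3 replicates of FLAG-DICER PAR-CLIP with RNase T1 in HEK293 cells, numbered as in the labels, with no second group. The labels do not say whether the replicates came from separate cultures, so the spread between them, which the sign-flip tests measure, may be technical. The other p-values run over clusters, hairpins or genes and do not measure that spread. The submitters' processing notes name Bowtie2 2.1.0 and the hg19 genome build. Each replicate had 2 sequencing runs, per the labels and the file attributes, and each list by the authors covers both.

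The authors deposited 1 list of clusters per replicate and 1 series-wide list, made by a program named in the files' source field whose version is not given in the sources used here. Per the file attributes, each cluster carries an estimated false discovery rate of 5%, the replicate lists were filtered by length, and every cluster of the series-wide list had reads from 2 or 3 replicates. The main value of each cluster is the deposited count of T-to-C conversions, a whole number not normalised to depth. The authors also gave an entropy score per cluster, which was read and not used for any result. This score was 0 for 1.40%, 64.6% and 80.6% of clusters in replicates 1, 2 and 3, and for 3.37% of the series-wide list. By the file attributes, 51.5%, 92.1% and 99.5% of clusters in replicates 1, 2 and 3 had reads from both sequencing runs. The lists thus differ in make-up, and whether they were selected alike was not tested. Read numbers, distinct reads and the annotation of both strands came from the deposited attribute text. Conversions are the authors' own values and were compared between lists as shares of each list's total, which is the total of listed clusters and not the sequencing depth. The series-wide list was not the sum of the replicate lists.

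Each cluster received 1 of 12 classes from the annotation in the files, in a fixed order: rRNA, tRNA, miRNA hairpin, snoRNA, snRNA, other structured small RNA, mitochondrial, mRNA exon, noncoding exon, intron, antisense and intergenic. The order, the gene lists and the main tests were set before the data were examined. Some details were set after the files' annotation had been seen: pseudogene exons stayed within noncoding exons, mRNA exon required an exon of a coding transcript, a cluster in several regions or genes counted as such for each, and symbols of snRNA, snoRNA and structured RNA genes were added to the repeat names, after the clusters with the most conversions had been seen. Symbols alone placed 4, 6 and 2 clusters in the snRNA class and 16, 8 and 3 in the snoRNA class in replicates 1, 2 and 3. They also placed 16, 16 and 10 clusters among other structured small RNAs, with 39.8%, 22.0% and 19.9% of all conversions, nearly all on the vault RNAs (39.5%, 21.8% and 19.8%). Where files named a mitochondrial rRNA or tRNA as a repeat, that class came first.

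Clusters were called overlapping when they shared at least 1 nt on the same strand. The background was 100 random placements of each cluster within a window of 10 kb around it, and the overlap with the opposite strand. The placements were not held within exons or transcripts, so they do not give the chance overlap within the same RNA. Classes were tested with Fisher's exact test, two-sided, in each replicate, and called only when all 3 replicates passed 0.05 after Benjamini-Hochberg adjustment in the same direction. Log2 odds ratios had 0.5 added to each count. Conversions of shared and unshared clusters were compared by the difference of median log2 values with 100000 resamples. Differences between classes or regions were tested by exact two-sided sign-flip permutation, which cannot go below 0.25 with 3 replicates; 6 such tests were made, all with a raw and adjusted value of 0.25.

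Each of the 15 gene lists was scored by its members with a cluster in all 3 replicates, against 10000 random lists of the same size from genes of the same kind, two-sided, with adjustment over the lists. Matching of random lists on exon length and the division of region shares by annotated length had been planned, but both need an annotation of the hg19 build, which was not used here. Gene symbols were matched by name alone to the RefSeq table of assembly GRCh38.p14, and 88.2%, 84.6% and 87.6% of the gene names in the 3 replicates matched. Of the 386 hairpin names, 381 matched. The genes named were, for each class, up to 4 with the most conversions in the series-wide list among clusters overlapped in all 3 replicates, a few members of each fixed list by the same ranking together with members without a cluster, and DICER1. XIST was left out of this rule, and 1 mRNA that it names is not reported here.

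The overlap, class, score and list calculations were tested on simulated data. For 400 clusters the overlap equalled a direct count in 100% of cases. In 200 simulated sets without class differences, 2.5% had any class called, and a class made 3 times as frequent among shared clusters was called in 100% of 200 sets. Of 200 random gene lists 1% had a p under 0.05, and of 200 score comparisons without a difference 3% did. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

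Median distinct reads per cluster were 3, 2 and 2 in replicates 1, 2 and 3, and 48.2%, 72.1% and 81.2% of clusters had exactly 2. Reads without molecular identifiers cannot be taken as independent molecules, so intervals cover counting error only. The alternatives set with them were a stricter list of clusters at or above the median conversions, an overlap of at least 0.5 of the cluster, merging of overlapping clusters, weighting by length, mRNA exons ahead of small RNAs, the series-wide list for gene lists, and leaving out each replicate. Weighting by distinct reads, a minimum of 3 distinct reads, distinct reads as the score and random lists from genes with a cluster were added after the data were seen. Tests of opposite-strand overlap, of the DICER1 regions, of splice sites and of Alu repeats were also chosen after the data were seen.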

Results

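DICER is the RNase III enzyme that cuts precursor miRNA hairpins in the cytoplasm, and the comparisons below ask which RNAs it touched in human cells. The RNAs came from Flp-In HEK293 T-Rex cells, an established line derived from human embryonic kidney, that carried a FLAG-tagged DICER transgene. In PAR-CLIP, cells take up a photoreactive uridine analogue, ultraviolet light links the labelled RNA to the bound protein, and the sites read as T-to-C changes after sequencing. All 3 samples formed 1 group of replicates, labelled T1 for the RNase of this protocol, so values are given per replicate or as mean ± SD (n = 3). The deposited lists held 11577 clusters of overlapping reads in replicate 1, 18065 in replicate 2 and 5099 in replicate 3, with 1306125, 1060791 and 595487 T-to-C conversions. A series-wide list of clusters with reads from at least 2 replicates held 8469. Reads were heavily repeated, with 18.6 reads per distinct read in replicate 1, 17.8 in replicate 2 and 33.8 in replicate 3. The totals may therefore overstate the number of separate molecules. Copies of 1 molecule could not be told apart from separate molecules with the same ends. No library without the tagged protein and no measure of RNA abundance was used here, so conversions mix binding with abundance.

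Vault RNAs, tRNAs and miRNA hairpins carried most of the conversions, while mRNA exons and introns made up most of the clusters. tRNA clusters were 4.89% ± 1.90 of clusters and held 39.4% ± 16.6 of conversions (SD, n = 3). Other structured small RNAs, a class of vault, Y, 7SL and related RNAs, were 0.777% ± 0.226 of clusters and held 27.6% ± 10.95 of conversions (SD, n = 3). miRNA hairpins were 2.95% ± 1.22 of clusters and held 14.03% ± 1.78 of conversions (SD, n = 3). These 3 classes together held 76.3% to 84.8% of conversions in the replicates. mRNA exons were 48.2% ± 10.9 of clusters with 8.78% ± 2.21 of conversions, and introns were 23.6% ± 8.58 of clusters with 4.05% ± 1.52 of conversions (SD, n = 3). The miRNA hairpin share of conversions exceeded its share of clusters by 11.1 percentage points ± 1.79 and the tRNA share by 34.5 ± 16.9, in 3 of 3 replicates each (exact two-sided sign-flip permutation p = 0.25, adjusted p = 0.25, the smallest that 3 replicates allow; 6 such tests were made). mRNA exons exceeded introns by 24.6 percentage points ± 19.2 of clusters, again in 3 of 3 replicates but with 46.5, 16.3 and 10.8 in replicates 1, 2 and 3, and 13.6 without replicate 1 (exact sign-flip permutation p = 0.25, adjusted p = 0.25). rRNA held 2.32% ± 3.37 of conversions, with 6.20% in replicate 1 and 0.373% without it. Counted by distinct reads, a weighting chosen after the data were seen, tRNA held 32.3% ± 4.63, mRNA exons 20.2% ± 3.95, introns 10.4% ± 3.98, other structured small RNAs 9.17% ± 1.72, miRNA hairpins 8.39% ± 0.511 and rRNA 7.68% ± 6.97, with 15.7% in replicate 1 and 3.66% without it. Among clusters with 3 or more distinct reads, a limit also chosen after the data were seen, tRNA made up 15.8%, miRNA hairpins 7.61%, other structured small RNAs 1.86% and introns 15.0% of clusters.

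**Figure D1:**
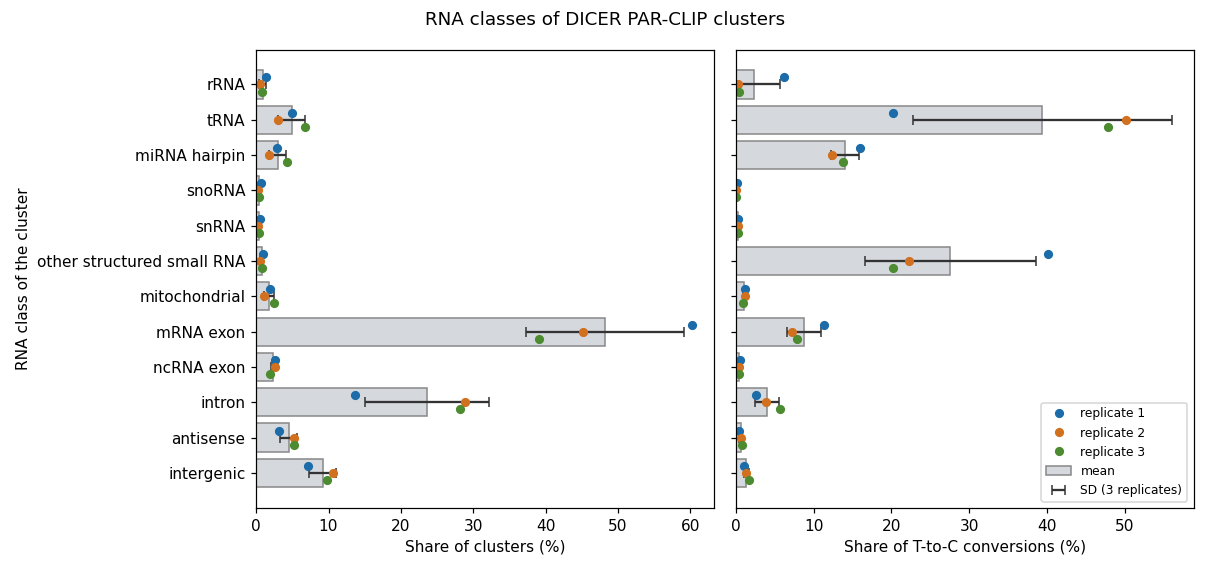
Share of clusters (left, percent) and of T-to-C conversions (right, percent) in each RNA class; bars are means over 3 replicates, lines the SD (drawn no lower than 0) and points the replicates. On the mean, mRNA exons lead the clusters at 48.2% and tRNA the conversions at 39.4%; in replicate 1 other structured small RNAs held 40.1% of conversions and tRNA 20.2%.

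Of the clusters in the series-wide list, that on VTRNA1-2, a short noncoding RNA of the vault particle, had the most conversions. The cluster (hg19 chromosome 5, 140098485 to 140098606, plus strand) held 31.2% of all conversions in replicate 1, 17.0% in replicate 2 and 16.1% in replicate 3, and 573744 conversions in the series-wide list. It ranked 1 by conversions in replicates 1 and 3 and 2 in replicate 2, behind a valine tRNA repeat, and by distinct reads it held 4.74% ± 1.56 of the total (SD, n = 3). VTRNA1-1 (140090847 to 140090997) held 2.75% ± 1.40 and VTRNA1-3 (140105735 to 140105866) 2.83% ± 0.955 of conversions, and the VTRNA1 genes together held 27.0% ± 10.8 (SD, n = 3). Among tRNAs, the valine tRNA on chromosome 5 (anticodon AAC, 180615436 to 180615496, minus strand) held 1.52% ± 0.528 and the valine tRNA on chromosome 19 (anticodon CAC, 4724634 to 4724727, minus strand) 1.64% ± 1.10 of conversions. The isoleucine tRNA on chromosome 6 (anticodon TAT, 27599187 to 27599312, plus strand) held 2.14%, 0.449% and 0.269% in replicates 1, 2 and 3, with a mean of 0.952% ± 1.03 (SD, n = 3) and 0.359% without replicate 1.

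Single repeat loci took very different shares in the 3 replicates. A valine tRNA repeat within a gene listed as AC073283.4 (chromosome 2, 47507893 to 47507935, minus strand) held 0.529% of conversions in replicate 1, 17.9% in replicate 2 and 13.3% in replicate 3, but 0.781% ± 0.413 of distinct reads (SD, n = 3). Without it, tRNA held 19.8%, 39.2% and 39.8% of conversions in the 3 replicates. A large-subunit rRNA repeat on chromosome 19 (24184087 to 24184152, minus strand) held 3.97% of conversions in replicate 1, 0.0239% in replicate 2 and 0.107% in replicate 3. Whether reads of these repeats belong to other copies of the same sequence was not tested.

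snRNA and snoRNA clusters held few conversions. snRNA clusters held 0.287% ± 0.0489 of conversions (SD, n = 3), led by the spliceosomal RNA RNU2-2 at 0.134% ± 0.0419 (chromosome 11, 62609076 to 62609233, minus strand). RNU12, of the minor spliceosome, held 0.0273% ± 0.0104. snoRNA clusters held 0.0744% ± 0.0204 of conversions, led by SNORA33 at 0.0148% ± 0.00814 (chromosome 6, 133138425 to 133138487, within RPS12). Of the 15 structured noncoding RNAs in the fixed list, 11 had a cluster in all 3 replicates against 0.915 on average in random lists (permutation p = 0.0002, adjusted p = 0.000375, the smallest p that 10000 random lists can give). They included RNY5, with 1806, 1524 and 428 conversions, and RMRP, the RNA of RNase MRP, with 234, 141 and 41. RN7SK, RNY3 and TERC had no cluster in any replicate.

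miRNA hairpins, the known substrates of DICER, had clusters at 313 loci in replicate 1, 298 in replicate 2 and 192 in replicate 3. In total 160 hairpins had a cluster in all 3 replicates, 97 in 2 and 129 in 1, and the series-wide list named 301. The 10 hairpins with the most conversions in the series-wide list held 70.4% ± 7.78 of hairpin conversions but 34.2% ± 3.85 of hairpin distinct reads (SD, n = 3). hsa-mir-20a, of the miR-17-92 cluster (chromosome 13, 92003325 to 92003385, plus strand), had 72507, 17972 and 6817 conversions in replicates 1, 2 and 3. hsa-mir-221 (chromosome X, 45605607 to 45605671, minus strand) had 14716, 40011 and 39618. By distinct reads hsa-mir-20a held 0.392% ± 0.0934 and hsa-mir-221 0.335% ± 0.113 of all reads, against 2.80% ± 2.40 and 3.85% ± 2.76 of all conversions (SD, n = 3); the first was 1.42% without replicate 1 and the second 2.45% without replicate 3. hsa-mir-106b and hsa-mir-93, which lie together within MCM7 on chromosome 7, had 1.11% ± 0.303 and 0.447% ± 0.134 of all conversions but on the mean more distinct reads than those 2, at 0.509% ± 0.0182 and 0.519% ± 0.132 (SD, n = 3). Over the 160 shared hairpins, log2 conversions correlated between replicates 1 and 2 with Pearson r = 0.863 and Spearman rho = 0.883, between 1 and 3 with r = 0.740 and rho = 0.739, and between 2 and 3 with r = 0.874 and rho = 0.831. Each permutation p was 1e-05 and each adjusted p 1e-05 over the 3 pairs, the smallest that 100000 resamples can give; these correlations are across hairpins, which are not independent replicates. Without the 2 hairpins farthest from the median, r was 0.864, 0.735 and 0.856. Chi-square values over these hairpins (67116, 86011 and 12581 with 159 degrees of freedom) exceeded the counting error of conversions, which with reads this repeated does not exclude that 1 library was amplified again.

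**Figure D2:**
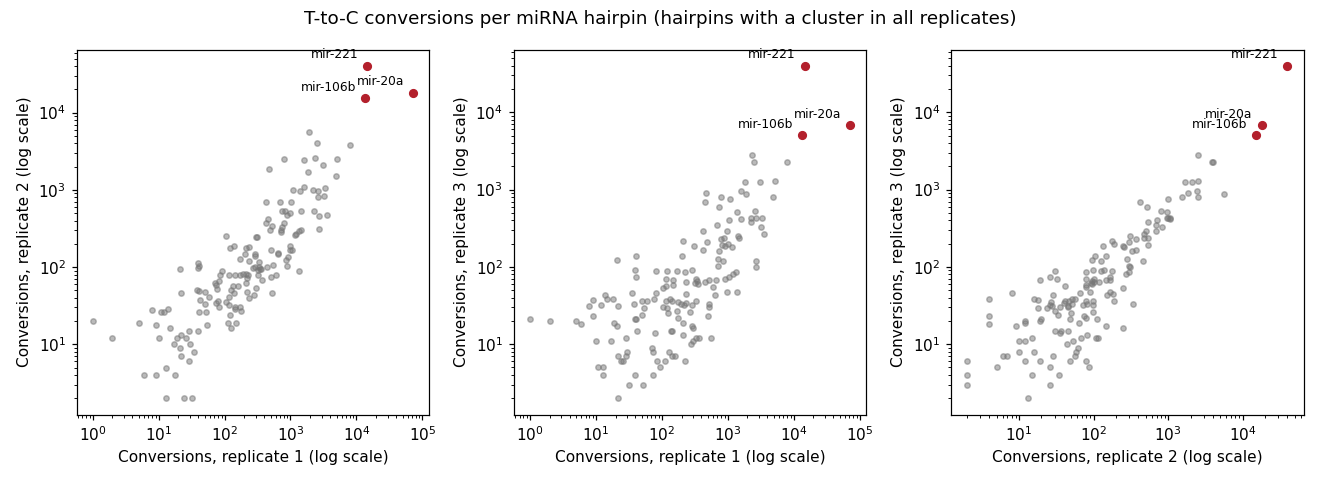
T-to-C conversions per miRNA hairpin in 1 replicate against another, on log axes, for the 160 hairpins with a cluster in all 3 replicates; each point is a hairpin, and the 3 with the most conversions in the series-wide list are red. hsa-mir-221 lies highest in replicates 2 and 3, and hsa-mir-20a in replicate 1.

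The lists of the miR-17-92 family, the let-7 family and other miRNAs expected in HEK293 cells had more members with a cluster in all 3 replicates than random lists of miRNA genes, but only the third also passed against miRNA genes with a cluster in any replicate (permutation adjusted p = 0.001). In the miR-17-92 family and its paralogs, which promote proliferation, 9 of 15 members had a cluster in all 3 replicates, against 1.23 in random lists (permutation p = 0.0002, adjusted p = 0.000375). MIR18B, MIR363 and MIR92A2 had none in any replicate. In the let-7 family, 8 of 12 members had one, led by MIRLET7A3 with 2659, 978 and 432 conversions, against 0.994 in random lists (permutation p = 0.0002, adjusted p = 0.000375). Of 53 other miRNAs expected in HEK293 cells, 40 had one, against 4.37 in random lists (permutation p = 0.0002, adjusted p = 0.000375); MIR222, MIR26B and MIR423 followed MIR221, and MIR218-2 had none. Among 22 miRNAs of noncanonical origin, such as mirtrons, hairpins from other noncoding RNAs and MIR451A, which is known to bypass DICER and had a cluster in replicate 1 alone (7 conversions), 5 had a cluster in all 3 (permutation p = 0.061, adjusted p = 0.0832), which did not pass. The largest of these was MIR1226, a mirtron excised by splicing, with 2370, 2556 and 2798 conversions, followed by MIR484, MIR320A, MIR664A and MIR1229. This list passed without replicate 1 (permutation adjusted p = 0.0292), without replicate 3 (adjusted p = 0.0305) and in the series-wide list (10 of 22, adjusted p = 0.0015). It did not pass without replicate 2 (permutation adjusted p = 0.0862) or with 3 or more distinct reads (2 of 22, adjusted p = 0.976). Among clusters at or above the median conversions (2 of 22) it did not pass either. Against random lists drawn only from miRNA genes with a cluster in any replicate, chosen after the data were seen, the miR-17-92 and let-7 lists no longer passed (permutation adjusted p = 0.0737 and 0.274). Nor did the noncanonical list pass there.

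Lists of markers of other tissues had no more members with a cluster in all 3 replicates than random lists, with 2 against 2.06, 1 against 1.25 and 0 against 0.475. Of 25 miRNAs typical of muscle, liver, brain, blood and other tissues, 20 had no cluster in any replicate, among them MIR1-1, MIR122 and MIR124-1, and 2 had one in all 3 replicates (permutation p = 1, adjusted p = 1). These were MIR146A, with 873, 472 and 234 conversions, and MIR9-2, with 15, 16 and 38. Of 27 mRNAs of other cell types, 25 had none, ALB, PTPRC and INS included. The muscle creatine kinase mRNA CKM had a coding-sequence cluster at the same place in all 3 (chromosome 19, 45818813 to 45818836, minus strand; 183, 14 and 15 conversions; permutation p = 1 and adjusted p = 1 for the list). None of 10 neuronal mRNAs had a cluster in all 3 replicates (permutation p = 1, adjusted p = 1), and NEFL had 1 in replicates 1 and 2.

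Among mRNAs, clusters lay mostly in 3' untranslated regions. The 3' untranslated region held 51.9% ± 1.30 of mRNA exon clusters, the coding sequence 27.2% ± 0.511 and the 5' untranslated region 8.84% ± 1.71, with 12.05% ± 0.211 touching more than 1 region (SD, n = 3). The 3' untranslated share exceeded the coding share by 24.6 percentage points ± 1.28, in 3 of 3 replicates (exact two-sided sign-flip permutation p = 0.25, adjusted p = 0.25, the smallest that 3 replicates allow). The mRNA clusters with the most conversions lay in GSG2, which encodes the kinase haspin (chromosome 17, 3627403 to 3627435, plus strand, coding sequence), at 0.102% ± 0.0669 of conversions, and in DCAF7 (chromosome 17, 61667869 to 61667941, plus strand, 3' untranslated region), at 0.0773% ± 0.0784, or 0.0336% without replicate 1. RPL37A (chromosome 2, 217366725 to 217366784) held 0.0525% ± 0.0276. The shares are not divided by the length of each region, because annotated lengths in the files' build were not used here. Among clusters with 3 or more distinct reads the 5' untranslated share was 14.2%.

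The DICER1 transcript carried more clusters than any other mRNA in each replicate, nearly all in its coding sequence. It had 33, 42 and 9 clusters in replicates 1, 2 and 3, with 2371, 1634 and 389 conversions, or 1.61%, 2.14% and 0.834% of those in mRNA exons. Over the replicates, 82 of these 84 clusters lay in the coding sequence alone, 2 also touched another annotated region, and 0 lay in introns or in the 3' untranslated region alone. The series-wide list held 36 DICER1 clusters, 34 of them in the coding sequence alone. Of its others, 1 touched another region and 1 lay in the 3' untranslated region alone. In other mRNAs, 27.5%, 26.5% and 26.7% of clusters lay in the coding sequence; the difference passed Fisher's exact test in each replicate, a test chosen after the values were seen (exact p = 3.29e-17, 8.82e-23 and 7.44e-06, adjusted p = 4.94e-17, 2.65e-22 and 7.44e-06). The cells carried a tagged DICER transgene, and its reads were not separated from those of the endogenous gene. Clusters in the coding sequence alone may come from the transgene. The Fisher test therefore cannot tell whether the endogenous transcript differs from other mRNAs. Its units are clusters of 1 gene, which are not independent. DROSHA, the nuclear enzyme that cuts primary miRNAs, had 1 exonic cluster in each replicate, at the same place in the coding sequence (chromosome 5, 31515530 to 31515593 in the series-wide list, minus strand; 458, 151 and 169 conversions). LIN28B, which blocks let-7 maturation, was the third of 22 small RNA pathway genes with a cluster in all 3 replicates (3 of 22, permutation p = 0.149, adjusted p = 0.186), and AGO4 and XPO5 had none. The list passed without replicate 1 (5 of 22, permutation adjusted p = 0.0249), without replicate 3 (10 of 22, adjusted p = 0.0024), among clusters at or above the median conversions (3 of 22, adjusted p = 0.0333) and in the series-wide list (15 of 22, adjusted p = 0.0003). It did not pass without replicate 2 (4 of 22, permutation adjusted p = 0.0723) or with 3 or more distinct reads (2 of 22, adjusted p = 0.0527). Nor did it pass against random lists from genes with a cluster.

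**Figure D3:**
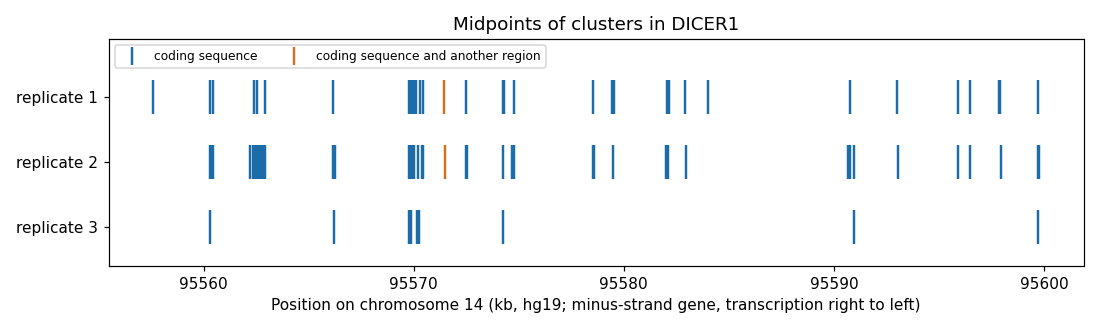
Midpoints of clusters in DICER1 along chromosome 14 (kb, hg19) in each of 3 replicates; each tick is a cluster, blue in the coding sequence alone and orange where another annotated region overlaps. The 33, 42 and 9 clusters follow the coding exons, with 2 orange ticks in all.

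Histone, ribosomal protein, housekeeping and sterol mRNA lists had more members with a cluster in all 3 replicates than random lists, and of these only the ribosomal protein list passed with 3 or more distinct reads. Histone mRNAs, which end in a stem-loop, had a cluster in all 3 replicates for 11 of 19 members, led by H4C2 with 421, 22 and 87 conversions, against 0.900 in random lists (permutation p = 0.0002, adjusted p = 0.000375). Ribosomal protein mRNAs did so for 14 of 58 members, led by RPS19 with 366, 207 and 101 conversions, and housekeeping mRNAs for 11 of 29, led by the elongation factor EEF2 with 474, 158 and 102 (permutation p = 0.0002, adjusted p = 0.000375 each). Of 17 sterol and endoplasmic reticulum stress mRNAs, 4 did so (CALR, FASN, SCD and XBP1; permutation p = 0.0152, adjusted p = 0.0228). Among long noncoding RNAs, NORAD alone of 17 did so, with 252, 75 and 4 conversions (permutation p = 0.0102, adjusted p = 0.017); only 31.5% of the noncoding exon gene names could be matched to current symbols, which lowers its random lists. With 3 or more distinct reads per cluster, 1 histone, 2 housekeeping and 0 sterol mRNAs were found in all 3 replicates (permutation adjusted p = 0.432, 0.0806 and 1), 3 ribosomal protein mRNAs (adjusted p = 0.043) and 0 long noncoding RNAs. Among clusters at or above the median conversions, the sterol list (2 of 17, permutation adjusted p = 0.163) and the long noncoding list (0 of 17) did not pass either. Against random lists from genes with a cluster, the ribosomal protein, sterol and long noncoding lists did not pass (permutation adjusted p = 0.053, 0.61 and 1). Without replicate 3, the counts were 31 ribosomal protein, 20 housekeeping, 8 sterol and 7 long noncoding.

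Mitochondrial RNAs gave clusters on both strands. Mitochondrial clusters held 1.10% ± 0.152 of conversions (SD, n = 3), and 10 of 13 mitochondrial mRNAs had one in all 3 replicates (permutation p = 0.0002, adjusted p = 0.000375). The largest cluster lay on the plus strand opposite MT-TP, the proline tRNA gene, at 15955 to 16097 in replicates 2 and 3 with no gene annotated in sense, and at 15830 to 16169 in replicate 1, where it also covered MT-CYB and MT-TT. It had 6190, 5433 and 2535 conversions. The MT-TP cluster on the minus strand had 844, 684 and 130. Of all clusters on the mitochondrial genome, 76.4%, 80.2% and 29.7% overlapped a cluster on the opposite strand of the same replicate. On the other chromosomes 0.176%, 0.134% and 0.121% did. Clusters are dense on the mitochondrial genome, and random shifts of 1 strand along it gave 67.5%, 73.5% and 23.7% on average, a comparison chosen after the overlap had been seen.

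**Figure D4:**
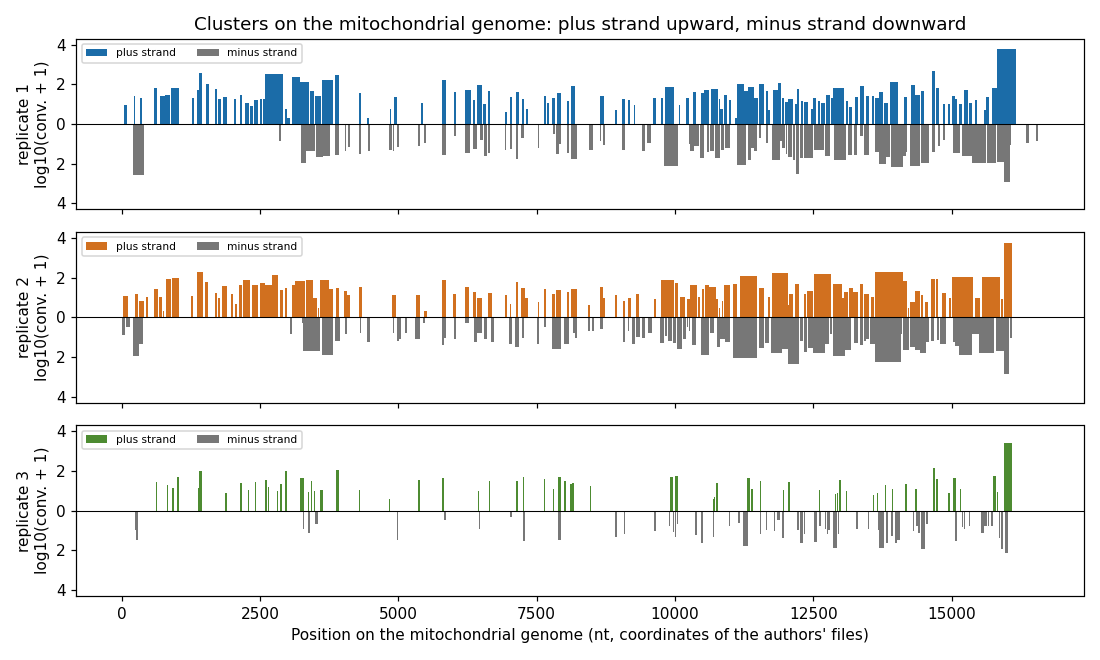
Clusters along the mitochondrial genome (position in nt) in 3 replicates, with bar width the cluster and bar height log10 of conversions plus 1; plus-strand clusters point up and minus-strand clusters down. The highest bar in each replicate lies near position 15955 on the plus strand, with 6190, 5433 and 2535 conversions.

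Intron clusters took 13.7% of the list in replicate 1, 28.9% in replicate 2 and 28.2% in replicate 3. Among intron clusters overlapped in all 3 replicates, that in SART1, a splicing factor gene, had the most conversions in the series-wide list. It (chromosome 11, 65744041 to 65744099, plus strand) held 0.0765% ± 0.0370 of conversions. RAB34 (chromosome 17, 27042964 to 27043010, minus strand) followed at 0.0422% ± 0.0454, or 0.0161% without replicate 1. NUTF2 (chromosome 16, 67902316 to 67902383, plus strand) came next at 0.0451% ± 0.0242 (SD, n = 3). Antisense clusters held 0.647% ± 0.195 and intergenic clusters 1.35% ± 0.314 of conversions. Noncoding exons held 0.431% ± 0.0494, among them clusters in NUPL1 and FBXW5 that also lie in introns of the coding transcripts of these genes.

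Most clusters of a replicate were not found in both others. A cluster overlapped clusters of both other replicates in 11.8% of cases in replicate 1 (95% Wilson interval 11.3 to 12.4), 7.51% in replicate 2 (7.13 to 7.90) and 27.9% in replicate 3 (26.7 to 29.2). Averaged over the 6 ordered pairs, 25.2% ± 11.5 (SD) of clusters overlapped the other list by at least 1 nt on the same strand, against 1.80% in random placements within 10 kb and 1.41% on the opposite strand. Each pair passed (permutation p = 0.0099, adjusted p = 0.0099, the smallest that 100 placements can give). These shares depend on list length: 9.79% of the clusters of replicate 2 overlapped replicate 3, and 36.2% of the clusters of replicate 3 overlapped replicate 2. Between clusters with 3 or more distinct reads, the mean over pairs was 47.2%. With 10 or more distinct reads, 61.1%, 70.5% and 98.6% of clusters overlapped both others.

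tRNA, miRNA hairpin and mitochondrial clusters had the highest odds of being found in both other replicates. The shares were 62.1% ± 19.3 for tRNA, 60.6% ± 18.4 for miRNA hairpins and 59.2% ± 29.8 for mitochondrial clusters, with mean log2 odds ratios of 3.78 ± 0.50, 3.52 ± 0.47 and 3.68 ± 1.43 (SD, n = 3). rRNA, other structured small RNA and snRNA were also higher, with log2 odds ratios of 2.32, 2.36 and 1.61. mRNA exons (-1.04), noncoding exons (-0.90) and intergenic clusters (-1.24) were lower. These 9 of 12 classes passed Fisher's exact test in 3 of 3 replicates over 36 tests, with the largest adjusted p 1.14e-113 for tRNA, 5.05e-63 for miRNA hairpins, 3.79e-29 for mitochondrial clusters, 0.0416 for snRNA and 0.0449 for noncoding exons (exact). snoRNA, intron and antisense clusters did not pass in all 3 (largest exact adjusted p 1, 0.125 and 0.0616). Shared clusters are mostly the same loci in each list, so the 3 tests of a class are not independent. Classes also differ in depth, which these tests did not hold fixed. Median distinct reads for tRNA, miRNA hairpin and mitochondrial clusters were 13, 6 and 9 in replicate 1 and 8, 4 and 2 in replicate 3. For mRNA exons, noncoding exons and intergenic clusters the median was 2 in each replicate. Mitochondrial clusters are also dense, covering 48.2%, 56.6% and 12.9% of the plus strand in replicates 1, 2 and 3. Overlap from that density alone was not set against these odds. With an overlap of at least 0.5 of the cluster, the mitochondrial log2 odds ratio was 2.53, against 2.54 for other structured small RNA. The mRNA exon call ended without replicate 3 (log2 odds -0.36), the noncoding exon call without any 1 replicate (-0.40, -0.65 and -0.40), among clusters at or above the median conversions and with 3 or more distinct reads, and the snRNA call without replicate 2, with an overlap of 0.5 of the cluster and with 3 or more distinct reads. The rRNA and other structured small RNA calls also ended with 3 or more distinct reads (1.20 and 1.45), while without replicate 1 snoRNA (1.47), intron (-1.49) and antisense clusters (-0.85) passed, as did antisense clusters without replicate 2 (-1.04).

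**Figure D5:**
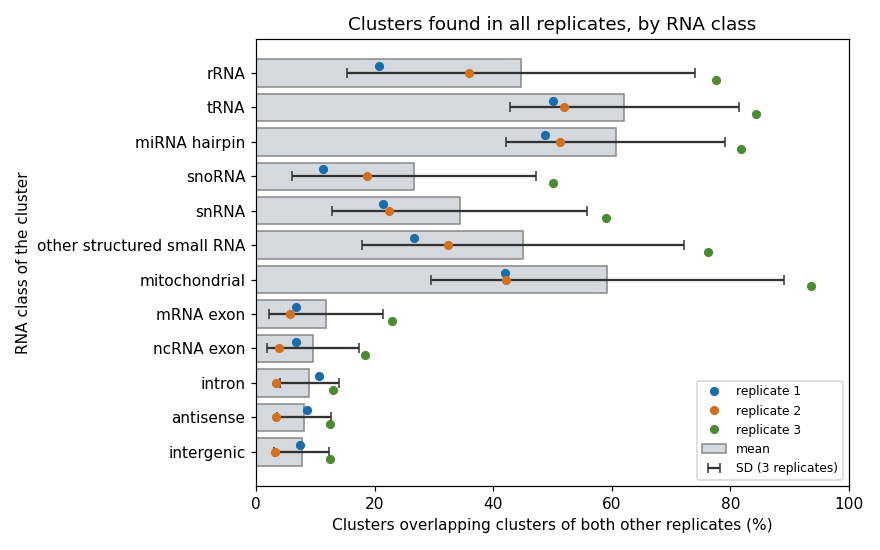
Share of clusters in each RNA class that overlap clusters of both other replicates (percent); bars are means over 3 replicates, lines the SD (drawn no lower than 0) and points the replicates. tRNA, miRNA hairpin and mitochondrial clusters average 62.1%, 60.6% and 59.2%, and mRNA exons 11.7%.

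Clusters found in all replicates also had more conversions. Their median was 46 conversions in replicate 1, 29 in replicate 2 and 28 in replicate 3, against 10, 5 and 16 for clusters found in 1 replicate. The log2 medians differed by 2.20, 2.54 and 0.81 (two-sided permutation test over clusters, p = 1e-05 and adjusted p = 1e-05 in each, the smallest that 100000 resamples can give). The mean of 1.85 ± 0.92 fell to 1.11 without replicate 2 and to 1.14 without replicate 3. Without replicate 1 the differences were 1.93 in replicate 2 and 0.585 in replicate 3. When a replicate is left out, a shared cluster is one that overlaps the only other list, so the groups compared change. Of the series-wide list, 15.9% of clusters overlapped clusters of all 3 replicates (95% Wilson interval 15.1 to 16.7), 37.6% of 2, 32.1% of 1 and 14.4% of 0. The share overlapping at least 2 was 53.5%, and 20.7%, 18.8% and 45.8% without replicate 1, 2 or 3, which leaves fewer lists to overlap. Its 2298766 conversions were 77.6% of the sum over the replicate lists, and 1849 of its clusters had reads from all 3 replicates.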

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

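Weighting by distinct reads, the minimum of 3 distinct reads, distinct reads as the score and random lists from genes with a cluster were chosen after the data were seen; the cause of each shift was not tested. Lists limited to clusters at or above their median conversions held 5894, 10616 and 2636 clusters, by construction. That limit also moved the share of the series-wide list overlapping 2 or 3 replicates from 53.5% to 62.8%, coding sequence clusters to 25.4% and 3' untranslated clusters to 55.1%. Overlap of at least 0.5 of a cluster gave 49.2% for that share, and leaving out 1 replicate, which leaves fewer lists to overlap, 18.8% to 45.8%. With 3 or more distinct reads, pair overlap rose to 47.2%, that share fell to 43.5%, and clusters became 15.8% tRNA, 7.61% miRNA hairpin, 1.86% other structured small RNA and 15.0% intron. Conversions then were 5.04% mRNA exon and 1.93% intron; mRNA regions were 14.2% 5' untranslated, 22.8% coding and 49.97% 3' untranslated; 3 classes stayed enriched among shared clusters and 6 lists passed. Weighted by distinct reads, shares were 32.3% tRNA, 8.39% miRNA hairpin, 9.17% other structured small RNA, 20.2% mRNA exon and 10.4% intron. Against genes with a cluster, 5 lists passed in place of 10. Classes depleted among shared clusters were 1 to 4 when a replicate was left out, 1 without replicate 3. The log2 ratio of observed to random members, with 0.5 added to both, went from 1.57 to -0.0040 for long noncoding RNAs with the stricter list and to -0.0029 with 3 distinct reads, and from 1.79 to -0.33 for sterol mRNAs with 3 distinct reads; each of these is a count of 0, whose sign the added 0.5 sets. The other 106 values of main results kept their direction and side of the threshold or stayed within their spread. Among the remaining values, single classes, lists and clusters, 481 did so, 50 moved, 19 lost and 11 gained a call; 258 of 282 values of the named clusters did not move. The hairpin alternative by cluster length was not run, since hairpin positions are not in the tables used, and unmatched random lists equal the main ones. Depth limits what the lists can show: replicate 3 had 296 clusters with 10 or more distinct reads.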

Other observations

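The values on splice sites, Alu repeats and conversion rates, the tests of intron shares expected from depth and among intron and mRNA exon clusters, and the p-values of mitochondrial shifts were chosen after the data were seen; the 3 patterns weighed further on were noticed in these data. Exon and intron clusters that spanned a 5' splice site outnumbered those at a 3' splice site, with 201 against 114 in replicate 1, 241 against 132 in replicate 2 and 82 against 27 in replicate 3. The ratio was 2.21 ± 0.718 (SD, n = 3; exact two-sided sign-flip permutation p = 0.25, the smallest that 3 replicates allow). Of the 5' splice site clusters 24.4%, 21.2% and 46.3% overlapped clusters of both other replicates, against 12.3%, 9.09% and 18.5% at 3' splice sites. Clusters antisense to Alu repeats alone outnumbered those in sense alone by 1.26 ± 0.121 times (SD, n = 3; exact sign-flip permutation p = 0.25), in 3 of 3 replicates.

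tRNA and rRNA clusters had fewer conversions per read than the other classes given here. Each read in a miRNA hairpin cluster held 0.929 ± 0.0267 conversions on average, in other structured small RNA 0.929 ± 0.00423, in mRNA exons 0.941 ± 0.0516, in tRNA 0.418 ± 0.0307 and in rRNA 0.212 ± 0.0210 (SD, n = 3). T-to-C made up 97.4% ± 1.23 of all mismatches in miRNA hairpin clusters and 98.1% ± 0.456 in other structured small RNA, against 59.8% ± 3.51 in tRNA and 40.5% ± 2.22 in rRNA. On the mitochondrial minus strand, 86 of 93, 83 of 95 and 56 of 63 clusters lay in no gene annotated on that strand.

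Few clusters of a replicate overlapped clusters of both others, and 2 explanations were tested. Chance overlap of clusters spread evenly over 10 kb is argued against. The mean over random placements was at most 1.81% in any replicate, 0.0649 to 0.0666 of the observed share, and the highest single placement reached 2.20%. Chance overlap within the same exons or transcripts was not tested, because the placements were not held there. Thin sampling of molecules is consistent with the data, since at least 61.1% of clusters with 10 or more distinct reads overlapped both others in every replicate. Such clusters are also richer in small RNAs, at 52.6%, 50.5% and 80.1%, so sampling and RNA class stay mixed. No biological explanation was tested, because the design has 1 group.

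Intron clusters took a larger share of the lists of replicates 2 and 3 than of replicate 1. The lists also differ in the share of clusters with an entropy score of 0. Whether that difference bears on the intron shares was not tested. As counted by distinct reads alone, the mix of thinly and deeply sampled clusters in each list is argued against as the whole cause. With the intron shares of replicate 1 at each depth, 14.6% and 14.9% of clusters would be intronic in replicates 2 and 3. These lie at least 13.3 percentage points below the observed 28.9% and 28.2%. The comparison takes a given number of distinct reads to mean the same in each list, which was not tested. The lists differ in entropy scores and in the share of clusters with reads from both runs, so other differences in sampling are not covered. Whether thinly sampled clusters carry the excess cannot be told apart from other causes. With 10 or more distinct reads the intron shares differed from replicate 1 by at most 2.27 percentage points, within the bound of 3 set beforehand. But small RNAs made up 52.6%, 50.5% and 80.1% of these clusters, against 2.97%, 1.51% and 4.95% with exactly 2. They left less room for a difference than at that depth, most of all in replicate 3. As a share of all clusters, the excess was largest with exactly 2 distinct reads, at 33.3% and 31.2% against 15.7%. At 3 to 9 the shares were 19.3% and 18.7% against 12.6%. Among intron and mRNA exon clusters alone, introns exceeded replicate 1 at every depth. They made up 42.5% and 41.8% against 19.1% with exactly 2, and 27.0% and 41.5% against 16.9% at 3 to 9. With 10 or more they made up 34.9% and 58.5% against 27.3% (Fisher's exact test over clusters, adjusted p = 0.0306 and 0.00013 over 6 tests, which covers counting error only). On that measure the excess of replicate 3 was not largest with exactly 2. No biological explanation was tested.

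Mitochondrial clusters were often faced by a cluster on the opposite strand. A candidate explanation is the high density of clusters on the mitochondrial genome, of which 48.2%, 56.6% and 12.9% was covered on the plus strand. Shifting 1 strand along the genome at random gave faced shares of 67.5%, 73.5% and 23.7% on average, below the observed 76.4%, 80.2% and 29.7%, and in 14 of the random placements over the 3 replicates, 100 in each, the share was as large as observed. The share was above the random mean in 3 of 3 replicates, but no replicate passed (one-sided permutation p = 0.0297, 0.0495 and 0.0891, adjusted p = 0.0743, 0.0743 and 0.0891), so density reaches most of the share and the remainder stays open. No biological explanation was tested.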
